A study of Mus musculus with 6 samples.

How the data were processed

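RNA-seq libraries of small-intestinal ILC3s from wild-type mice, 3 treated with vehicle and 3 with PEox, were analysed from 1 deposited table of gene counts. Per the labels' protocols, libraries were made and sequenced by a company on an Illumina NovaSeq instrument as paired reads of 150 bp, reads were cleaned with fastp, and they were aligned with HISAT2 2.0.5 to a reference genome. The submitters' processing notes also name edgeR 3.22.5. The read counter, the genome build, the annotation and whether the libraries keep strand were not given in the sources used here, so no coordinates are printed, and overlapping or antisense genes and near-identical copies are uncertain because reads of one could be counted for another. The deposited values were raw counts per gene, whole numbers with no normalization, for 55401 Ensembl gene identifiers, of which 29431 had a count in any library. All count columns were matched to samples by their titles, and 0 columns of samples were left unused.

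Gene symbols were looked up by identifier in a reference table of gene names, which named 55141 identifiers and left 260 under their identifier. The unnamed identifiers held 0.015% to 0.0191% of the counts of a library. Libraries were grouped by their treatment label. Total counts ranged from 56252806 to 66849230, so that 3 counts, used as the floor for a gene with no count, equal 0.045 to 0.053 CPM per library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Counts of any pair of libraries of a group differed by more than the sampling noise of independent reads. The chi-square per gene was 16.6 to 38.9 within groups and 274 to 355 between them. Each library was kept as 1 replicate, although this excess cannot show that the libraries came from separate samples.

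Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the group, which left 18253 genes, and libraries were scaled by TMM factors between 0.951 and 1.05. PEox was compared with vehicle by the robust quasi-likelihood test, with group as the single term, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The common biological coefficient of variation was 34.5%. Standard errors are the log2 fold change divided by the root of the F statistic. CPM values use the TMM factors and are given as mean ± SD. Gene lists were compared with all other genes by camera on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and at least 3 tested members, adjusted over 44 lists, and again with an estimated correlation. List medians were also computed with genes at 0 in all PEox libraries set to their bound, which left every list median as it was.

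The design, the 44 lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Named genes were 12 fixed genes, the 8 with the largest and the 8 with the smallest log2 fold change among changed genes with a mean of at least 5 CPM and no overlap between the groups (predicted genes, pseudogenes and antigen receptor segments left out), and for each list up to 4 members with the smallest p-values. Genes outside this rule are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

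The alternatives were RLE scaling, scaling by library size, no low count filter, a filter of at least 5 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, an estimated correlation and camera on ranks. A removal of the trend of each library on transcript length and GC content, by loess with a span of 0.5, was added after the data were seen. Transcript lengths came from a GENCODE mouse transcript set that held 99.9% of the tested genes and may differ from the annotation behind the counts.

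The procedure was tested on simulated data for the comparison of PEox with vehicle, drawn with 200 single genes changed and 1 list of 30 other genes raised by 0.5 on the log2 scale, 230 in all, among 17466 tested genes. Of 100 genes changed by 1 on the log2 scale 68% were recovered, and of 100 changed by 2 it was 78%. Of 17236 unchanged genes 9 were called, and of 20 unchanged lists 0 were called, while the raised list was called higher (camera adjusted p = 9.22e-25, preset correlation). Simulated genes were drawn independently of each other, so this check cannot show how the list test behaves where genes are correlated. Far fewer genes were changed in it than the 6775 called in the data. In a second simulation of 17453 genes, removal of an imposed length trend lowered the calls from 1923 to 0.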

Results

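RNA from mouse group 3 innate lymphoid cells (ILC3s) was sequenced in 6 libraries. ILC3s are lymphocytes without antigen receptors that reside in mucosal tissue and release interleukin 22 (IL-22) and interleukin 17. Per the labels, the cells came from the small-intestinal lamina propria of wild-type mice and had been treated beforehand with PEox or with vehicle, with 3 libraries in each group. The labels do not spell PEox out; in research on ferroptosis, an iron-dependent cell death driven by lipid peroxidation, it is the usual abbreviation for oxidised phosphatidylethanolamine. The dose, the exposure time and whether the cells were exposed inside or outside the animal were not given in the sources used here. The deposited count table held 66849230, 59524577 and 65747460 counts in vehicle libraries 1 to 3 and 56252806, 56542297 and 57532484 in PEox libraries 1 to 3. The vehicle libraries had 23486, 23239 and 23605 genes with a count, and the PEox libraries 21983, 21895 and 22182. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

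The cell type label named ILC3s, whereas the protocol text named sorted epithelial cells carrying EpCAM and lacking CD45, so the identity of the libraries was examined first. Transcripts of ILC3s dominated over those of epithelium in all 6 libraries. The 24 ILC3 core genes, among them the cytokine receptor genes Il7r and Il23r, summed to 12170 ± 153 CPM (counts scaled to library depth; SD, n = 3) in vehicle and 8770 ± 34.3 (SD, n = 3) in PEox. The intestinal epithelium list, which holds Epcam and keratin genes, summed to 120.9 ± 7.91 CPM (SD, n = 3) in vehicle and 79.53 ± 2.11 (SD, n = 3) in PEox. The enterocyte list summed to 325 ± 0.551 CPM in vehicle and 289.1 ± 7.56 in PEox (SD, n = 3 each), of which Dgat1, a triglyceride synthesis gene that is not restricted to enterocytes, held 297.6 and 272.3 CPM. Goblet, Paneth, enteroendocrine and tuft cell genes summed to 32.63 ± 4.13 and 32.07 ± 1.45 CPM (SD, n = 3 each). These sums carry no test.

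The comparison of PEox with vehicle asked how the treatment altered the transcriptome of ILC3s, in a series whose title concerns the bile acid receptor FXR, epithelial ferroptosis and ILC3 dysfunction in neonatal necrotizing enterocolitis. In the PEox libraries Il22, which encodes the epithelium-protecting cytokine IL-22, fell from 6724 ± 63.5 to 2513 ± 59.4 CPM (SD, n = 3 each), a log2 fold change of -1.42 ± 0.03 (SE; adjusted p = 3.79e-07, edgeR quasi-likelihood test). Genes of cell division, ribosomal proteins, the respiratory chain, interferon responses and antigen presentation were lower alongside it, by a list test with a preset inter-gene correlation. With an estimated correlation none of these lists passed: adjusted p = 0.0525 for cell cycle, interferon and MHC class II genes, 0.202 for ribosomal proteins, 0.141 for the respiratory chain and 0.272 for MHC class I. Glutathione and antioxidant genes were higher by the same test (adjusted p = 0.0686 with an estimated correlation), with 17 of 30 rising and 6 falling. Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, rose from 86.5 ± 2.70 to 308 ± 8.25 CPM (SD, n = 3 each), while the glutathione peroxidase gene Gpx1 fell by 0.93 on the log2 scale. Markers of B cells, mast cells and myeloid cells were lower in the PEox libraries as well, while erythroid genes, among them haemoglobin genes, were higher. With an estimated correlation these lists did not pass either, at adjusted p = 0.0525, 0.109, 0.126 and 0.335 in that order.

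Of 18253 genes tested, 6775 (37.1%) changed at an adjusted p under 0.05 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3337 higher and 3438 lower in PEox. At least a 2-fold change was found for 685 of the higher and 1274 of the lower genes. The groups' CPM values did not overlap for 9238 genes, 50.6% of those tested, where chance gives 10%. Scaling by library size alone, which shifted the median log2 fold change of all tested genes to 0.14, gave 4411 higher and 2715 lower genes (61.9% higher, against 49.3% with TMM scaling), so directions are relative to the scaling used. Correlations of log2 CPM across genes lay between 0.993 and 0.994 for pairs of vehicle libraries, between 0.986 and 0.987 for pairs of PEox libraries and between 0.963 and 0.968 across the groups; genes are not independent replicates.

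Among the genes fixed for naming beforehand, effector genes of ILC3s moved in both directions while several receptors did not pass the test. Il17f, an interleukin 17 family cytokine gene, rose from 589 ± 7.60 to 992 ± 14.8 CPM (SD, n = 3 each; log2 fold change 0.75 ± 0.03, SE; edgeR adjusted p = 3.33e-06). Il17a lay at 2.25 ± 0.54 CPM in vehicle and 3.12 ± 0.89 in PEox (SD, n = 3 each) and did not pass, at a log2 fold change of 0.47 ± 0.32 (SE; edgeR adjusted p = 0.308). Without PEox library 2 that fold change was 0.21 (edgeR adjusted p = 0.675). Csf2, which encodes the myeloid growth factor GM-CSF, fell by 0.76 on the log2 scale (edgeR adjusted p = 0.000181). Ccr6, the chemokine receptor gene of lymphoid tissue inducer-type ILC3s, dropped by 1.27 (edgeR adjusted p = 2.59e-06), and Ncr1, which encodes the NKp46 receptor, dropped by 2.23 (edgeR adjusted p = 0.00365). The log2 fold changes of Il23r (-0.08, adjusted p = 0.412), Ahr (-0.11, adjusted p = 0.366) and Il7r (-0.17, adjusted p = 0.0511) did not pass the edgeR test. The signs of Il23r and Ahr turned under library size scaling, to 0.05 and 0.03. When each library was left out in turn, Il23r ran from -0.12 to -0.01 and Ahr from -0.20 to -0.05. With the length and GC trend removed, Il23r was called lower at -0.34 (adjusted p = 0.00659) and Il7r at -0.32 (adjusted p = 0.00339). Il7r was also called lower with DESeq2 (adjusted p = 0.0328), limma-voom (0.0421), the stricter filter (0.022) and without PEox library 2 (0.0153). Under library size scaling it lay at only -0.04 (edgeR adjusted p = 0.689).

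Lists of genes fixed beforehand were then compared with all other genes using limma camera with a preset inter-gene correlation. Of 44 lists tested, 21 were called at an adjusted p under 0.05, of which 3 were higher and 18 lower in PEox. No list was called when the correlation was estimated per list, so every list call rests on the preset value, and the estimated-correlation p is given with each.

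The ILC3 cytokine genes were lower as a group. Of 19 members tested, 11 fell, 2 rose and 6 did not pass the gene test (adjusted over the list alone, 11 and 2), and the median log2 fold change was -0.69 (camera adjusted p = 0.000602, and adjusted p = 0.0836 with an estimated correlation). With the stricter filter the median was -1.15. Lta and Ltb, which encode the lymphotoxin subunits needed for lymphoid tissue, fell by 1.70 and by 1.14 on the log2 scale. Ccl4, a chemokine gene, fell from 58.7 ± 3.29 to 1.57 ± 0.18 CPM (SD, n = 3 each), a log2 fold change of -5.22 ± 0.13 (SE). Genes of the natural cytotoxicity receptor (NCR) subset of ILC3s were also lower, with 9 of 15 falling, 1 rising and 5 not passing (adjusted over the list alone, 9 and 1). The median was -0.69 (camera adjusted p = 0.00214, and adjusted p = 0.126 with an estimated correlation). Within that list the cytotoxic protease gene Gzmb dropped by 2.44, Xcl1 by 3.82, Ccl5 by 1.84 and Ifng, the interferon gamma gene, by 3.34. The NCR genes summed to 2080 ± 81.3 CPM in vehicle and 1779 ± 74.3 in PEox (SD, n = 3 each). The lists share members, 11 of the 20 cytokine genes and 7 of the 15 NCR genes standing in another list. Gzmb also stands in the list of ILC1 and natural killer cells. Counts of B cell, T cell and natural killer cell markers, given further on, were lower in the same libraries.

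Members of the ILC3 core list went both ways. Of 24 genes 12 fell, 5 rose and 7 did not pass (adjusted over the list alone, 14 and 5), with a median of -0.21 (camera adjusted p = 0.0481, and adjusted p = 0.169 with an estimated correlation). That median was -0.08 with library size scaling and -0.34 with the length and GC trend removed (adjusted p = 0.0127). Besides Lta and Ltb, the short-chain fatty acid receptor gene Ffar2 fell by 2.53 and the arginase gene Arg1 by 1.36, while Kit, a growth factor receptor gene, rose by 0.91 on the log2 scale. The list call was also lost with RLE scaling (adjusted p = 0.0509), with library size scaling (0.092), on ranks (0.0814), with replicate blocks (0.074) and without vehicle library 2 (0.0791), PEox library 1 (0.136) or PEox library 2 (0.0597).

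Lymphoid tissue inducer (LTi) genes had a median of -0.84, with 9 of 17 members falling, 5 rising and 3 not passing (adjusted over the list alone, 9 and 5), and the list was not called (camera adjusted p = 0.111). Cd74, the invariant chain of MHC class II, fell by 1.34, whereas Tnfsf4, which encodes the co-stimulatory ligand OX40L, rose by 2.21. IL-23 and STAT3 signalling genes were not called (median -0.06, camera adjusted p = 0.79), with 8 of 23 falling and 5 rising (adjusted over the list alone, 9 and 6). Their median was 0.08 with library size scaling, -0.01 with the stricter filter and -0.34 with the length and GC trend removed. Among them the adaptor gene Myd88 fell by 0.66 and Il12rb1, a subunit of the IL-23 receptor, by 0.69, while the kinase gene Tyk2 rose by 0.85, or 0.55 with the length and GC trend removed. Targets of the aryl hydrocarbon receptor (AhR) had a median of 0.38 and 5 of 9 rose while 1 fell (adjusted over the list alone, 5 and 2; camera adjusted p = 0.111, not called). Adhesion and homing genes were not called either (median -0.41, camera adjusted p = 0.154), with 12 of 21 falling and 6 rising (adjusted over the list alone, 12 and 6). Of these the chemokine receptor genes Ccr2, Ccr9 and Cxcr6 dropped by 1.29, 1.18 and 0.41, and Cxcr6 lay at -0.27 under library size scaling. The adhesion and homing median was -0.27 under that scaling. Checkpoint and inhibitory receptor genes split evenly (median -0.41, and -0.08 with the stricter filter), with 4 of 12 rising and 4 falling (adjusted over the list alone, 4 and 4; camera adjusted p = 0.595); Lilrb4a dropped by 1.92 and Pdcd1, the PD-1 gene, rose by 0.46.

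Receptors for neuropeptides and vitamins were higher as a group, with 7 of 12 rising, 1 falling and 4 not passing (adjusted over the list alone, 7 and 1). The median was 0.55 (camera adjusted p = 0.0162, and adjusted p = 0.15 with an estimated correlation). Vipr2, a receptor gene for vasoactive intestinal peptide, rose from 9.78 ± 2.39 to 37.5 ± 6.73 CPM (SD, n = 3 each), and Ret rose by 0.85 on the log2 scale, or 0.55 with the length and GC trend removed. Nmur1, the neuromedin U receptor gene, dropped by 1.54. Erythroid genes were higher in the same libraries (list median 0.96).

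**Figure D1:**
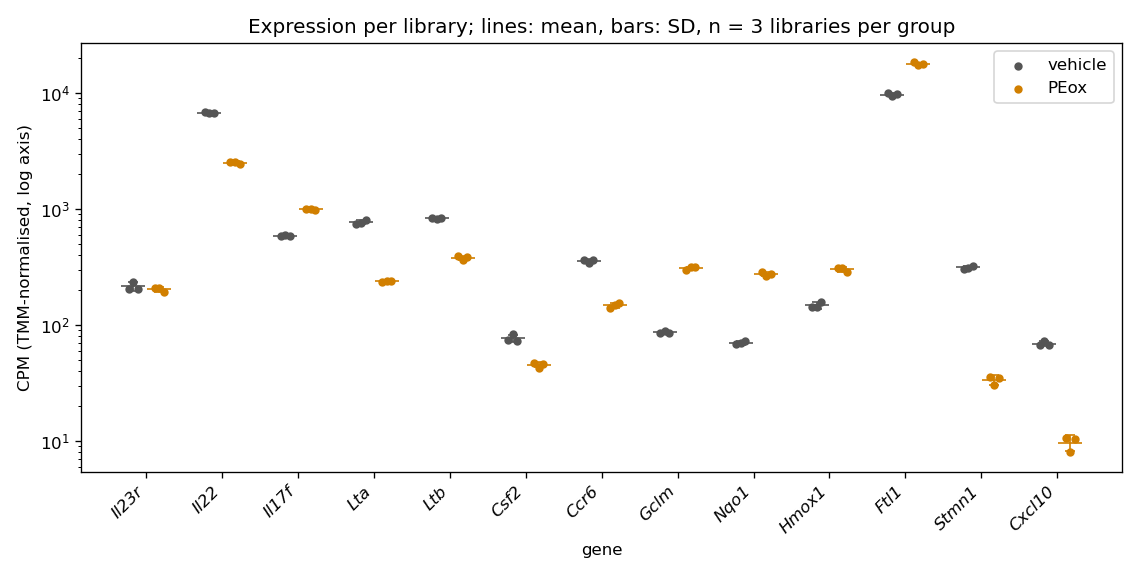
Expression of 13 genes in CPM with TMM scaling (log axis) in each of the 3 vehicle (grey) and 3 PEox (orange) libraries, with the mean as a line and the SD as a bar. Il22 lay at 6724 CPM in vehicle and 2513 in PEox on average, and Gclm at 86.5 and 308, whereas Il23r, at 214.8 and 203.0, did not pass the test.

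Genes of the NRF2 and glutathione programme, which counter oxidants, were higher in the PEox libraries, with 17 of 30 rising, 6 falling and 7 not passing (adjusted over the list alone, 20 and 6). The median was 0.61 (camera adjusted p = 0.000176, and adjusted p = 0.0686 with an estimated correlation). Nqo1, a quinone reductase gene, rose by 1.98 ± 0.06 on the log2 scale (SE), Gclm by 1.83 ± 0.05 (SE) and Gclc, the catalytic subunit of the same enzyme, by 1.46 ± 0.05 (SE). Gpx1 moved the other way and dropped by 0.93 ± 0.04 (SE). Erythroid genes were higher in the same libraries, with a list median of 0.96 and summed levels of 3069 ± 34 CPM in vehicle and 5742 ± 356 in PEox (SD, n = 3 each).

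Ferroptosis and iron genes divided, with 13 of 39 rising, 14 falling and 12 not passing (adjusted over the list alone, 15 and 16). The list was not called (camera adjusted p = 0.885), with a median of 0.08 and a mean of -0.20. That mean takes in 1 member with no count in any PEox library, whose fitted fold change is unbounded. The median was 0.22 with library size scaling and 0.03 with the stricter filter. Iron storage genes rose, Ftl1 from 9686 ± 251 to 17820 ± 428 CPM and Fth1 from 2495 ± 39.6 to 3790 ± 161 CPM (SD, n = 3 each). Hmox1, which encodes the haem-degrading enzyme, rose by 1.03 and Slc3a2, a subunit of the cystine importer, by 0.89 on the log2 scale. Gpx4, which encodes the enzyme that reduces lipid peroxides, fell from 752 ± 12.6 to 537 ± 19.6 CPM (SD, n = 3 each; edgeR adjusted p = 5.8e-05). Slc7a11, the other subunit of the cystine importer, rose by 1.27 ± 0.34 on the log2 scale (SE; edgeR adjusted p = 0.0182) at low levels of 4.57 CPM in vehicle and 11.02 in PEox. That call was lost without vehicle library 1 (adjusted p = 0.0774), vehicle library 2 (0.0802), PEox library 1 (0.0503) or PEox library 3 (0.0581).

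All 36 cell cycle genes fell (adjusted over the list alone, 36), with a median log2 fold change of -2.44 (camera adjusted p = 1.08e-18, and adjusted p = 0.0525 with an estimated correlation). Stmn1, a microtubule regulator gene, fell from 313 ± 10.4 to 33.7 ± 3.16 CPM (SD, n = 3 each), the replication helicase gene Mcm5 fell by 2.28, Ccnb2, a mitotic cyclin gene, by 4.09 and Ube2c by 3.63. Kif2c and Hmmr, mitotic spindle genes outside the list, dropped by 4.95 and 4.69. Markers of B and plasma cells (list median -2.49), mast cells, basophils and eosinophils (-1.68) and ILC1 and natural killer cells (-1.65) were lower in the same libraries. Replication-dependent histone genes were lower too, with 26 of 56 falling, 2 rising and 28 not passing (adjusted over the list alone, 26 and 2). The median was -1.33 (camera adjusted p = 3.97e-07, and adjusted p = 0.0525 with an estimated correlation). Hist1h2ap dropped by 2.39 and Hist1h2ao by 2.42, while the linker histone gene Hist1h1c rose by 1.03. Histone genes of one family are near-identical, so counts of single members are uncertain.

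Cytosolic ribosomal protein genes fell together, 83 of 88 with none rising (adjusted over the list alone, 85). The median was -1.14 (camera adjusted p = 3.89e-29, and adjusted p = 0.202 with an estimated correlation). Rps15 and Rpl12 dropped by 1.43 and 1.88. Nuclear-encoded respiratory chain genes fell in 73 of 77 cases, with 2 rising (adjusted over the list alone, 73 and 3). The median was -0.83 (camera adjusted p = 2.91e-21, and adjusted p = 0.141 with an estimated correlation), and Atp5o, Ndufb9, Cycs and Ndufb7 dropped by 1.14, 1.06, 1.10 and 1.04. Mitochondrially encoded genes were lower as well, 11 of 13 falling and none rising (adjusted over the list alone, 11). The median was -0.80 (camera adjusted p = 1.56e-05, and adjusted p = 0.272 with an estimated correlation). The mitochondrial share of counts was 1.81%, 1.83% and 1.63% in vehicle libraries 1 to 3 and 1.38%, 1.32% and 1.21% in PEox libraries 1 to 3. Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain in level. In the same libraries the marker lists of B and plasma cells (median -2.49), mast cells, basophils and eosinophils (-1.68) and ILC1 and natural killer cells (-1.65) were lower.

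Interferon response genes were lower, with 27 of 38 falling, 3 rising and 8 not passing (adjusted over the list alone, 29 and 3). The median was -0.95 (camera adjusted p = 3.18e-07, and adjusted p = 0.0525 with an estimated correlation). The chemokine gene Cxcl10 fell from 68.8 ± 3.30 to 9.66 ± 1.49 CPM (SD, n = 3 each), the immunoproteasome gene Psmb8 dropped by 0.97 and Irf1 by 0.86. All 10 MHC class II genes fell (adjusted over the list alone, 10). The median was -1.12 (camera adjusted p = 2.1e-06, and adjusted p = 0.0525 with an estimated correlation); H2-Aa, H2-Ab1 and H2-DMb2 dropped by 1.26, 1.03 and 2.33. MHC class II is expressed by ILC3s and also by B cells and myeloid cells, whose markers were lower in the same libraries (list medians -2.49 and -1.08). MHC class I genes fell in 10 of 14 cases with 1 rising (adjusted over the list alone, 10 and 1). The median was -0.42 (camera adjusted p = 0.0171, and adjusted p = 0.272 with an estimated correlation), and H2-K1 dropped by 0.46. NF-kB targets fell in 14 of 22 cases with 2 rising (adjusted over the list alone, 15 and 2). The median was -0.61 (camera adjusted p = 0.00102, and adjusted p = 0.109 with an estimated correlation). The inhibitor genes Nfkbia and Nfkbie dropped by 0.98 and 0.71 and the adhesion gene Icam1 by 1.54, while Nfkb1, which encodes a subunit of the factor, rose by 0.48, or 0.29 with the length and GC trend removed.

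**Figure D2:**
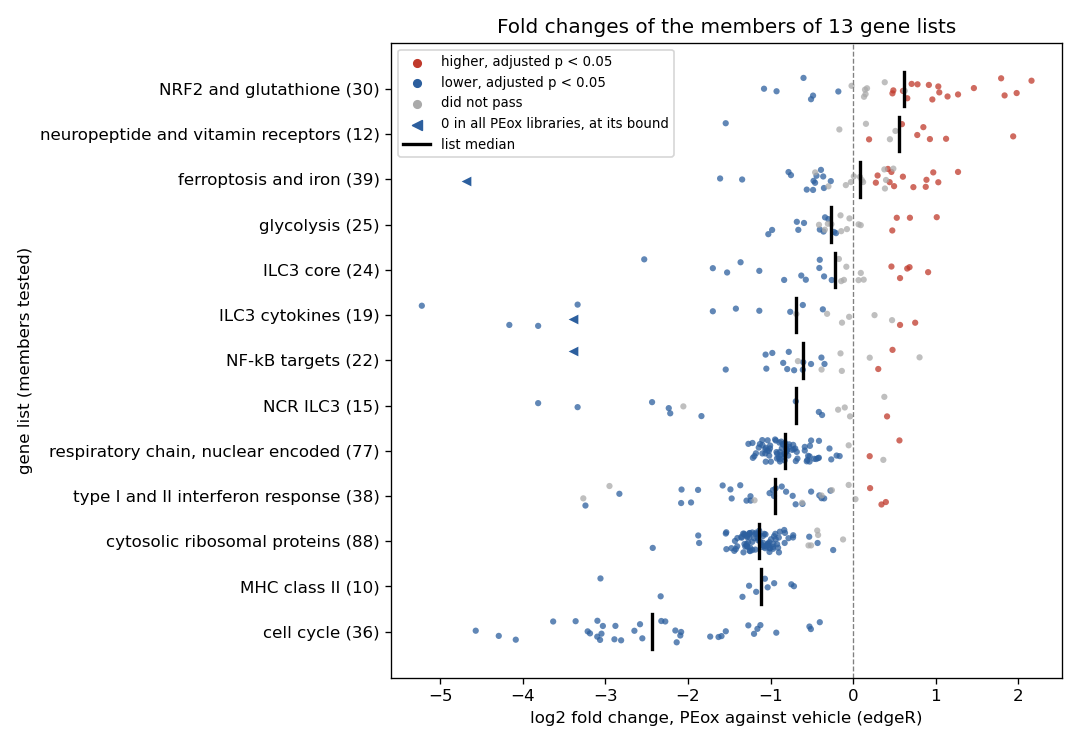
Log2 fold change of PEox against vehicle (horizontal axis) for each tested member of 13 gene lists (vertical axis), coloured by the edgeR call, with the list median as a black line and members with no count in any PEox library drawn as triangles at their bound. The median lay at -2.44 for cell cycle genes, -1.14 for cytosolic ribosomal proteins and 0.61 for NRF2 and glutathione genes.

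Metabolic lists outside the respiratory chain were not called. Glycolysis genes had a median of -0.26 (camera adjusted p = 0.0778), with 11 of 25 falling and 4 rising (adjusted over the list alone, 13 and 4), and the call was made without a low count filter (adjusted p = 0.0481). Ldha, the lactate dehydrogenase gene, fell from 2068 ± 88.9 to 1015 ± 28.4 CPM (SD, n = 3 each), whereas the hexokinase gene Hk1 rose by 0.53. Cholesterol synthesis genes had a median of -0.27 with 10 of 22 falling and 2 rising (adjusted over the list alone, 13 and 2; camera adjusted p = 0.111), and Fdps and Mvd dropped by 0.92 and 0.83. Fatty acid oxidation and uptake genes had a median of 0.11 with 7 of 25 rising and 4 falling (adjusted over the list alone, 7 and 4; camera adjusted p = 0.768). Cpt1a, which admits fatty acids to mitochondria, rose by 1.21 and Fabp5, a fatty acid binding protein gene, dropped by 2.74. For fatty acid and phospholipid synthesis, 4 of 27 genes rose and 6 fell (adjusted over the list alone, 4 and 6; camera adjusted p = 0.888), with a median of -0.05 although the test pointed higher; Acly rose by 0.70 and Fads1 by 1.07. Hypoxia genes had a median of 0.12 with 8 of 19 rising and 4 falling (adjusted over the list alone, 8 and 4; camera adjusted p = 0.275). Only 4 of 11 FXR targets were counted deeply enough to test, of which Pltp dropped by 1.47 and Nr0b2, Gpbar1 and Nr1h4 did not pass (adjusted over the list alone, 1 fell); the median was 0.39 and the test pointed lower (camera adjusted p = 0.978). Nr0b2, a gene that FXR is known to induce, lay at 0.04 ± 0.07 CPM in vehicle and 0.57 ± 0.30 in PEox (SD, n = 3 each; log2 fold change 3.67 ± 1.46, SE; edgeR adjusted p = 0.0851). It was called higher with DESeq2 (adjusted p = 0.0412), limma-voom (0.0438) and without vehicle library 3 (0.0207). Vehicle library 3 held its only vehicle counts, at 0.127 CPM against 0 in vehicle libraries 1 and 2. Leaving that library out thus left vehicle with no count of Nr0b2. Gpbar1, a bile acid receptor gene, was called higher without PEox library 2 (1.91, adjusted p = 0.0391), and limma-voom gave -0.47. Nr1h4, the FXR gene itself, lay at 0.51 ± 0.32 CPM in vehicle and 0.35 ± 0.11 in PEox (SD, n = 3 each), where the floor was 0.045 to 0.053 CPM per library. Library size scaling put the medians at -0.13 for glycolysis, -0.14 for cholesterol synthesis, 0.24 for fatty acid oxidation, 0.08 for fatty acid and phospholipid synthesis and 0.25 for hypoxia. Other medians were -0.08 for fatty acid oxidation and 0.02 for fatty acid and phospholipid synthesis with the stricter filter, 0.20 and 0.18 for fatty acid oxidation and hypoxia with the trend removed, and 1.32 (no low count filter) and 0.03 (replicate blocks) for FXR targets.

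Stress lists were mixed and none was called. Heat shock genes had a median of 0.24 with 8 of 15 rising and 4 falling (adjusted over the list alone, 8 and 5; camera adjusted p = 0.249). The inducible chaperone genes Hspa1a and Hspa1b rose by 2.20 and 2.39; their sequences are near-identical, so the split of reads between them is uncertain. Integrated stress response genes had a median of 0.07 with 6 of 22 rising and 7 falling (adjusted over the list alone, 7 and 7; camera adjusted p = 0.839), and unfolded protein response genes a median of -0.07 and a mean of 0.02 with 9 of 21 rising and 10 falling (adjusted over the list alone, 9 and 10; camera adjusted p = 0.888). Ppp1r15a rose by 0.84, Nupr1 fell by 0.95, Dnajb9 rose by 0.85 and Manf fell by 0.74. Apoptosis and p53 target genes had a median of 0.16 with 12 of 28 rising and 8 falling (adjusted over the list alone, 13 and 8; camera adjusted p = 0.281); the p53 targets Mdm2 and Ccng1 rose by 1.06 and 0.89 while Trp53 itself dropped by 0.73. Pyroptosis and necroptosis genes had a median of -0.10 with 5 of 17 falling and 1 rising (adjusted over the list alone, 5 and 1; camera adjusted p = 0.249), and the inflammasome adaptor gene Pycard dropped by 1.08. Immediate early genes, which respond to cell handling, had a median of 0.03 and a mean of -0.20 with 8 of 27 rising and 6 falling (adjusted over the list alone, 9 and 7; camera adjusted p = 0.72). Medians moved with the settings. They were 0.38 for heat shock, 0.21 for the integrated stress response, 0.06 for the unfolded protein response, 0.30 for apoptosis, 0.03 for pyroptosis and 0.16 for immediate early genes with library size scaling. With the length and GC trend removed they were 0.04 for heat shock, 0.01 for the integrated stress response, -0.18 for the unfolded protein response and -0.085 for immediate early genes. The stricter filter gave 0.03 for the integrated stress response, 0.25 for apoptosis, -0.42 for pyroptosis and 0.06 for immediate early genes. Pyroptosis genes had -0.17 with replicate blocks, and immediate early genes 0.01 without a low count filter.

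Extreme changes were sought among genes of at least 5 CPM on average, without overlap between the groups leaving out predicted genes, pseudogenes and antigen receptor segments. Among the largest rises were Arrdc3, an arrestin family gene, from 7.79 ± 0.30 to 106.0 ± 15.5 CPM (SD, n = 3 each; log2 fold change 3.77 ± 0.12, SE; edgeR adjusted p = 8.88e-07), then Alas2 (2.46), Sh3tc1 (2.43), Hspa1b (2.39), Procr (2.36), Tnfsf4 (2.21) and Hspa1a (2.20). Under the same conditions, Urah dropped by 6.44, the pre-B cell gene Vpreb3 by 5.99, Ccl4 by 5.22, Ankle1 by 5.17 and the immunoglobulin joining chain gene Jchain by 4.67; the call of Ankle1 was lost with DESeq2 (adjusted p = 0.0808), and in PEox it had counts in library 2 alone. One model under the symbol Sept2 (ENSMUSG00000116048) had no count in any PEox library and was at least 1580-fold lower, against a floor of 3 counts per library. A second model with the same symbol (ENSMUSG00000026276) was higher in PEox, at a log2 fold change of 1.82, so the reads of both are uncertain, and limma-voom did not call the first (adjusted p = 0.434).

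B and plasma cell genes summed to 936.9 ± 2.40 CPM in vehicle and 281.3 ± 6.59 in PEox (SD, n = 3 each), and 17 of 19 fell with none rising (adjusted over the list alone, 17). The median was -2.49 (camera adjusted p = 4.15e-08, and adjusted p = 0.0525 with an estimated correlation). Igkc, the kappa light chain gene, dropped by 3.54 and the B cell receptor gene Cd79a by 4.03. Mast cell, basophil and eosinophil genes fell in 7 of 13 cases with 1 rising (adjusted over the list alone, 8 and 1). The median was -1.68 (camera adjusted p = 0.000838, and adjusted p = 0.109 with an estimated correlation); Tpsb2, a mast cell tryptase gene, dropped by 3.35, Prss34 was at least 40.5-fold lower, the list call was lost with the stricter filter (adjusted p = 0.0701), and the median was -2.97 without PEox library 3. Macrophage, monocyte and dendritic cell genes fell in 10 of 20 cases with none rising (adjusted over the list alone, 10). The median was -1.08 (camera adjusted p = 0.000602, and adjusted p = 0.126 with an estimated correlation), with Lyz2 dropping by 1.12 and the plasmacytoid gene Siglech at least 75.3-fold lower. ILC1 and natural killer cell genes fell in 8 of 12 cases with none rising (adjusted over the list alone, 8). The median was -1.65 (camera adjusted p = 0.000362, and adjusted p = 0.104 with an estimated correlation), and Gzma dropped by 1.66. ILC2 genes fell in 5 of 12 cases with none rising (adjusted over the list alone, 5). The median was -0.41 (camera adjusted p = 0.0103, and adjusted p = 0.126 with an estimated correlation).

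T cell genes fell in 9 of 17 cases with none rising (adjusted over the list alone, 10). The median was -0.67 (camera adjusted p = 0.000478, and adjusted p = 0.0836 with an estimated correlation). The median was -1.05 without PEox library 1. Cd3g dropped by 1.47 and Trbc2 by 0.40, the latter lying at -0.26 under library size scaling; ILC3s can themselves carry transcripts of T cell receptor constant regions. Neutrophil genes were not called (median -0.52, camera adjusted p = 0.166), with 3 of 14 falling (adjusted over the list alone, 3), and Elane at least 33.2-fold lower. The list summed to 100.4, 92.9 and 28.1 CPM in vehicle libraries 1 to 3 and to 59.3, 28.7 and 123.2 in PEox libraries 1 to 3. Its median was -0.23 without vehicle library 1, -0.75 without vehicle library 3 (then called, adjusted p = 0.0235), -0.17 without PEox library 2, -0.99 without PEox library 3 and 0.27 with the stricter filter.

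Erythroid genes were higher, with 5 of 10 rising and none falling (adjusted over the list alone, 5). The median was 0.96 (camera adjusted p = 0.0091, and adjusted p = 0.335 with an estimated correlation). Hba-a1 rose from 1144 ± 7.11 to 2204 ± 116 CPM (SD, n = 3 each), Hbb-bt rose by 1.15 and Alas2, which starts haem synthesis in red cells, by 2.46; the haemoglobin genes have near-identical copies. Stromal and endothelial genes were not called (median 0.26, camera adjusted p = 0.111), with 6 of 17 rising and 3 falling (adjusted over the list alone, 6 and 3); the collagen genes Col3a1 and Col1a1 rose by 2.17 and 1.27 while the smooth muscle actin gene Acta2 dropped by 1.88. The stromal median was 0.40 with library size scaling, 0.57 with the stricter filter and 0.10 with the length and GC trend removed. Epithelial genes were not called (median -0.61, camera adjusted p = 0.147), with 4 of 14 falling and 1 rising (adjusted over the list alone, 4 and 1), and Epcam dropped by 0.71. Enterocyte genes (median -0.23, camera adjusted p = 0.51; 1 of 8 fell, and adjusted over the list alone 1) were not called. The same held for goblet, Paneth, enteroendocrine and tuft cell genes, none of whose 5 tested members passed (adjusted over the list alone, 0), with a median of 0.05 and a mean of -0.58 (camera adjusted p = 0.888). The enterocyte median was -0.09 with library size scaling, -0.70 with replicate blocks and -0.51 with the trend removed. For the goblet and related list it was 0.18 with library size scaling, 0.38 without a low count filter and 0.17 with the trend removed.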

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

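Removal of the length and GC trend was chosen after the data were seen, and all other settings before. The count of changed genes stayed within 1.5 times of 6775 under every setting run, from 5282 without vehicle replicate 2 to 7617 with DESeq2, and 5685 of the 6445 genes called with the trend removed were shared. Leaving out each library in turn gave 5282 to 6577 genes and 20 to 22 lists. With an estimated inter-gene correlation 0 lists were called, against 21 with the preset value, and the cause was not tested. The other settings called 20 to 22 lists. The ILC3 core list lost its call under RLE and library size scaling, on ranks, under the replicate block and without vehicle replicate 2, PEox replicate 1 or PEox replicate 2; elsewhere the mast cell list was lost with the stricter filter, the glycolysis list gained without a filter and the neutrophil list gained without vehicle replicate 3. The replicate block gave 6159 genes (5987 shared) and 20 lists, with the ILC3 core list at an adjusted p of 0.074. Deviations of libraries with equal numbers correlated weakly across genes, at 0.073, 0.032 and 0.042. Vehicle libraries 1 and 3 matched the PEox library of their own number best, while vehicle library 2 matched PEox library 3 best.

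The direction turned for lists and genes that were not called, and the cause was not tested. The values are list medians where the list test turned. With no low count filter they were 1.317 for FXR targets and 0.379 for goblet and related cells, with the stricter filter -0.078 for fatty acid oxidation and 0.272 for neutrophils, with library size scaling 0.064 for the unfolded protein response, and with the trend removed -0.085 for immediate early genes and 0.166 for goblet and related cells. For lists whose test turned when at least 1 library was left out, the medians over all 6 such settings, turned or not, ran from -0.075 to 0.069 for IL-23 and STAT3 signalling (turned without PEox replicate 2), -0.997 to 0.541 for FXR targets (turned without vehicle replicates 1 and 3 and PEox replicate 2), -0.136 to 0 for the unfolded protein response (turned without PEox replicate 1) and -0.114 to 0.772 for goblet and related cells (turned without any 1 vehicle replicate and without PEox replicate 3). As log2 fold changes, library size scaling gave 0.05452 for Il23r, 0.02588 for Ahr and 0.008213 for Dgat1, limma-voom gave -0.4661 for Gpbar1, and leaving out each library in turn gave -0.03999 to 0.1176 for Zg16. Leaving out 1 library moved the median by over 1.5 times for 2 of the 21 called lists, T cells and mast cells, and for 17 of the 23 lists not called. Summed CPM of the ILC3 core list moved to 11600 in vehicle and 9190 in PEox under library size scaling. Over all settings the named genes kept their direction and side of the threshold in 2552 instances, gained a call in 21, lost one in 21 and turned in 6. Genes near the floor of 0.045 to 0.053 CPM, such as most FXR targets, limit what can be read.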

Other observations

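The tests of a lower ILC3 share, of 1 pool of cells per group and of single pups were chosen after the results were seen, and the length and GC alternative and the repeat of the ILC3 share test under other settings were added then too. In the pool test, the condition that 2 PEox libraries must differ less than libraries of different groups was also added after its values were seen; without that condition the test would have favoured a shared pool.

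The genes Igll1 and Vpreb2, which encode parts of the surrogate light chain and were chosen after their values were seen, lay at 2.26 and 0.754 CPM in vehicle with no count in PEox, at least 44.9-fold and 14.9-fold lower against a floor of 3 counts per library. The granule protease genes Prtn3 and Ctsg, chosen likewise, were at least 16-fold and 12-fold lower. The 24 immunoglobulin V segments compared held 7131, 7068 and 7530 counts in vehicle libraries 1 to 3 and 266, 195 and 258 in PEox libraries 1 to 3. They were picked by a minimum count over the vehicle libraries. Segments high in PEox alone were thus left out, and part of this difference is built in. Igkv8-30 alone had 875, 881 and 891 counts in the vehicle libraries and 0, 6 and 0 in the PEox libraries, and Ighv5-9-1 had 881, 905 and 866 against 0 in each.

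Genes that differ with the sex of the cells, chosen after their values were seen, differed between the groups and so were confounded with the treatment. The ratio of Xist, expressed from the inactive X chromosome of female cells, to the Y-linked Ddx3y was 1.71, 2.01 and 1.91 in vehicle libraries 1 to 3 and 0.75, 0.81 and 0.72 in PEox libraries 1 to 3. Xist fell by 0.56 on the log2 scale, and the Y-linked genes Ddx3y, Uty and Kdm5d rose by 0.75, 0.95 and 0.53. With the length and GC trend removed Ddx3y lay at 0.44 and Kdm5d at 0.18, where it was not called (adjusted p = 0.281). The Y-linked Eif2s3y was not called under any setting, at 70.4 ± 8.63 CPM in vehicle and 63.8 ± 4.94 in PEox (SD, n = 3 each; edgeR adjusted p = 0.351, and 0.0903 to 0.98 over the other settings). A different mix of sexes in the 2 groups was thus neither shown nor excluded.

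The 6775 changed genes were set against all 10 splits of the 6 libraries into 3 and 3. Only 1 split, the real one, gave as many, and the highest of the others gave 1 gene. Every other split mixed vehicle and PEox libraries, which puts the difference between the groups into the spread within them. Few calls in those splits were thus built in. With 10 splits the share can never be under 0.1, so the splits are too few for a share under 0.05.

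The first pattern is the lower expression of ILC3 cytokine genes in PEox (adjusted p = 0.0836 with an estimated correlation). A lower share of ILC3s in the PEox libraries is argued against as the whole cause of the fall of Il22. The 21 ILC3 core genes that encode no cytokine had a median log2 fold change of -0.172, above -0.71, the change of Il22 divided by 2. The 95% bootstrap interval of that median, -0.409 to 0.066, resampled genes and not libraries, so it does not measure the spread between libraries. Medians of 12 lists of other cell types ran from -2.492 to 0.959, 9 of them below 0, where a lower ILC3 share alone would raise them alike. A smaller loss of ILC3s was not excluded. Only Il22 served as the yardstick, and it fell more than the cytokine list, whose median was -0.688. How far a lower share accounts for the list as a whole was thus not decided. Over all settings run, that core median lay between -0.339 (trend removed; interval -0.536 to -0.045, against -0.744) and -0.036 (library size scaling). A length and GC trend is argued against as the whole cause, since 4 of the 4 genes Il22, Lta, Ltb and Csf2 still passed with the trend removed, Il22 at -1.49. The treatment remains open, untested, and so does a difference between the cells that went into the 2 groups, which is confounded with it, as the ratio of Xist to Ddx3y above is.

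The second pattern is the lower expression of ribosomal protein and respiratory chain genes (adjusted p = 0.202 and 0.141 with an estimated correlation), in libraries where markers of B and plasma cells (median -2.492), mast cells (-1.677) and ILC1 and natural killer cells (-1.649) were lower too. Ribosomal and respiratory chain transcripts are short, and fold changes rose with transcript length across 10739 genes (Spearman's rho 0.25, -0.004 with the trend removed; genes are not independent replicates). With the trend removed the ribosomal median was -0.993 against -1.136, and the respiratory chain median -0.689 against -0.829, so the trend does not account for the whole pattern. The 95% bootstrap interval of that ribosomal median, -1.068 to -0.915, resampled genes and not libraries, so it does not measure the spread between libraries. The choice among TMM, RLE and library size scaling does not account for the lower ribosomal median, since the highest value under them was -1.0. Against TMM, RLE scaling shifted log2 fold changes by a median of only 0.006, and library size scaling by 0.136. Shifts that small could not have removed a median of -1.136, so nothing is concluded about other scalings. A shift of all genes that these scalings cannot see was not tested. The treatment, the mix of cells, the number of cells and the RNA quality per library remain open, untested.

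The third pattern is how close the libraries of a group lay, with correlations of 0.993 to 0.994 in vehicle. Single pups as the origin of each library are argued against, since Xist and the Y-linked Ddx3y were both present in all 6 libraries and the lower of them was never under 33.1 CPM. Libraries drawn from 1 pool of cells per group may explain the closeness, and V segment profiles thinned to 195 reads differed by at most 0.173 between 2 vehicle libraries against at least 0.415 between groups. The segments were picked by their vehicle counts, which can widen the gap between groups. However, 2 PEox libraries differed by 0.233 to 0.441, as much as some pairs from different groups, and the cause of that spread was not tested. For PEox, a shared pool and separate samples thus cannot be told apart. The spread in PEox does not bear on vehicle, where profiles with all reads differed by 0.049 to 0.062. What 1 pool would give at that depth was not computed. No libraries known to be separate were at hand to compare either, so for vehicle neither 1 pool nor separate samples were shown or excluded. If each group was 1 pool, the p-values would describe 2 pools and not a treatment effect over animals.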
